A study of Mus musculus with 30 samples.

How the data were processed

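RNA from 30 dishes of cultured mouse telencephalon was hybridized to Affymetrix Mouse Genome 430A 2.0 arrays, each with 22690 probe sets. The deposited values are signals computed by the authors with the Affymetrix MAS5 algorithm, in units of array intensity on a linear scale; the version of that software is not given. The series description speaks of a later division by the array median and of a filter on present calls in at least 50% of arrays. Neither is visible in the deposited intensity values, because the array medians ranged from 81.9 to 138 and all 22690 probe sets were listed. Every array therefore had its signals divided by its own median before further use. An array gives no count of molecules, so the number of arrays, 5 per group, limits the precision.

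Scaled signals below 0.1 of the array median were set to that floor and converted to log2. Of the probe sets, 20393 carried 1 gene symbol, 691 carried several and 1606 carried none; only the first kind was used. The brightest probe set on average stood for each of 12394 genes. The upper 60% of genes by mean log2 signal were tested, which left 7436. Symbols come from the platform annotation. Entrez identifiers were looked up in the RefSeq gene table of the mouse assembly GRCm38.p6, where 29 probe sets found no entry and no symbol changed; that table served only for chromosomes and neighbours.

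A linear model with 1 mean for each of 6 groups was fitted to all 30 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and an intensity trend. It gave 11 comparisons: 24 h and 48 h of BDNF against basal and 48 h against 24 h within each genotype, knockout against wild type at each of the 3 times, and the genotype difference in the response at 24 h and at 48 h. All tests were two-sided, and p-values were adjusted within each comparison over the tested genes by the Benjamini-Hochberg method, with a threshold of 0.05. "Rose", "fell" and "changed" are used for genes past it. The 48 h arrays of both genotypes share a day of lysis that differs from that of the basal arrays.

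Genes were named in the text by a rule. Xbp1 is given in every comparison. Each comparison within or between genotypes gives the 8 largest rises and the 8 largest falls among genes that passed the threshold and whose 5 arrays per group did not overlap. The genotype differences in response give all genes past the threshold. Each list gives up to 4 members past the threshold with the largest change. For GABAergic markers, every tested member of the lists of GABA synthesis and of interneuron peptides is given. Slc6a13, Pvalb, Vip, Cort, Nos1 and Htr3a were measured but left out by the filter on low genes, so they were not tested. Genes outside this rule are named as chosen after their values were seen.

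The analysis used 22 gene lists written from general knowledge: GABA synthesis and transport; interneuron peptides and calcium-binding proteins; GABAergic lineage transcription factors; GABA-A receptor subunits; glutamatergic and cortical projection neuron genes; pan-neuronal genes; immediate-early genes; ERK pathway feedback and target genes; secretory granule and neuropeptide genes; neurotrophins and receptors. Further lists held XBP1-dependent genes of the endoplasmic reticulum (ER) and secretory pathway, ATF4 and CHOP targets, cholesterol synthesis genes, cell cycle genes, neural progenitor genes, p53 targets and sex-linked genes, as well as markers of astrocytes, oligodendrocytes, microglia, vascular and meningeal cells and erythroid cells. The first 3 were also joined into a list of GABAergic markers. Lists with at least 3 tested members, 22 with the joined list, were compared with all other genes by camera with a preset correlation of 0.01, and again with a correlation estimated for each list. P-values of camera were adjusted over these 22 lists. The rotation test fry was run beside it.

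The choice of comparisons, the threshold, the rule for named genes, the lists and most alternatives were fixed before the data were examined. The alternatives were quantile normalization, scaling to the 75th percentile, values as deposited, a pseudocount or a lower floor, no filter or the upper 40% of genes, the mean of a gene's probe sets, only the arrays compared, replicate number as a block, no intensity trend, array weights, stricter thresholds and leaving out each array in turn. Chosen after the data were seen were the use of 48 h replicates 1 and 2 or 3 to 5 alone, a term for 48 h replicates 3 to 5, the Gapdh 3'/5' ratio as a covariate, exclusion of genes on X and Y, and the linear scale for GABAergic markers. The Gapdh ratio overlapped with the 48 h groups, as 8 arrays at 48 h lay below the range of all basal and 24 h arrays. A 48 h call lost with this covariate, or with fewer 48 h arrays, can therefore also reflect this overlap or lower power. The procedure was tested on simulated data with 50 changed genes at each of several sizes. At 1.5-fold it recovered 84% of them in a comparison of groups and 76% in a genotype difference of responses, and 4.05% and 5.70% of all calls were unchanged genes. The simulated noise was independent between genes, with no deviation common to an array, so these shares need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.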

Results

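Primary cultures of mouse telencephalon, the part of the embryonic brain that forms cortex and basal ganglia, were prepared at embryonic day 12.5. The pool of the knockout held cells of 6 embryos genotyped as knockouts of Xbp1, a transcription factor of the unfolded protein response, and the wild-type pool cells of 4 embryos. Each pool was divided over 15 dishes. BDNF, a neurotrophin that signals through the TrkB receptor, was added at 100 ng/ml on day 3 in vitro. Dishes without BDNF (basal) and dishes with 24 h of BDNF were lysed on day 4, and dishes with 48 h of BDNF on day 5, so that at 48 h BDNF and time in culture differed together. Each of the 6 groups held 5 dishes, with 1 array per dish. Before scaling, the median signal per array was 96.1 ± 6.71 intensity units in wild-type basal dishes and 119 ± 8.35 after 48 h (SD, n = 5). In the knockout it was 103 ± 6.77 and 122 ± 11.5. The Gapdh 3'/5' signal ratio, a measure of RNA integrity and labelling, was lower at 48 h, at 2.47 ± 0.09 in wild type and 2.39 ± 0.21 in the knockout against 2.86 ± 0.10 and 2.73 ± 0.10 in basal dishes. All p-values measure only the spread between dishes of 1 pool per genotype. Signals below are log2 values relative to the array median, and changes are log2 differences ± SE from limma.

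Xbp1 mRNA was detected in both genotypes. Its brightest probe set read 4.43 ± 0.04 in wild-type and 4.65 ± 0.07 in knockout basal dishes (SD, n = 5), a difference of 0.22 ± 0.06 (adjusted p = 0.0050). The knockout differed by 0.07 at 24 h and by 0.10 at 48 h, neither past the threshold (adjusted p = 0.370 and 0.233). In a fit of all probe sets, another Xbp1 probe set was higher in the knockout by 1.09 ± 0.10 without BDNF, 1.05 at 24 h and 0.85 at 48 h (adjusted p = 8.55e-09, 1.91e-08 and 5.06e-07), and the remaining ones did not pass. The labels do not say which part of the gene was removed, and a transcript without function can still bind these probes. Under BDNF, Xbp1 rose by 0.21 at 48 h in wild type (adjusted p = 0.0067), a call that was lost with the mean of its probe sets, with 48 h replicates 1 and 2 alone, with a term for 48 h replicates 3 to 5 and with the Gapdh ratio as a covariate. Its other changes under BDNF did not pass, with 0.12 at 24 h in wild type and -0.03 and 0.09 at 24 h and 48 h in the knockout; the last turned to -0.012 with quantile normalization. From 24 h to 48 h the Xbp1 difference was 0.09 in wild type and 0.12 in the knockout, and its response differed between genotypes by -0.15 ± 0.09 at 24 h and -0.12 ± 0.09 at 48 h, all short of the threshold.

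The first comparison asked which genes 24 h of BDNF changes in wild-type cells. Of the 8 largest rises 4 were in genes for neuropeptides or a granin. The peptide genes Npy and Pnoc rose by 2.23 ± 0.10 (4.68-fold, adjusted p = 3.60e-17) and 1.98 ± 0.09, the guidance gene Sema3e by 1.96 ± 0.16, Dlk1 by 1.64 ± 0.13, the peptide gene Cartpt by 1.61 ± 0.12, the granin Scg2 by 1.60 ± 0.08, Akr1b8 by 1.56 ± 0.09 and the ERK phosphatase Dusp6 by 1.49 ± 0.08 (n = 5). The largest falls were smaller, at -0.97 ± 0.17 for the guanylate cyclase subunit Gucy1a1, -0.95 ± 0.15 for Egfl6, -0.82 for Dglucy, -0.79 for Cd52, -0.78 for Prtn3 and for Sla, and -0.74 for Rnase4 and for St6gal1. In all, limma called 598 genes higher and 476 lower, of which 98 and 29 changed at least 1.5-fold. The share higher was 55.7%, against 48.4% with quantile normalization, 47.0% with scaling to the 75th percentile and 66.2% without rescaling. The 5 arrays per group did not overlap for 646 of these 1074 genes. Chance gives 0.794% for a gene that was not selected. Called genes were selected on the same arrays, here and below, so their share without overlap cannot be compared with that value.

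Of the 14 tested secretory granule and neuropeptide genes, 12 rose, among them Nptx1 (1.45) and Gal (1.246), and 13 did when adjusted over the list alone. Their mean change was 0.87 (adjusted p = 2.20e-20, and 0.0012 with an estimated correlation). Interneuron peptides and calcium-binding proteins averaged 0.72 (adjusted p = 3.67e-07, and 0.0091 with an estimated correlation), with Tac1 up by 1.196, Calb1 by 1.12 and Sst by 0.84. Of the 8 members 4 rose, and 5 adjusted over the list alone. The GABA-synthesizing enzymes Gad2 (0.76) and Gad1 (0.46) were among 3 of 4 genes of GABA synthesis and transport that rose, by either adjustment (list mean 0.43, adjusted p = 0.0027, and 0.049 with an estimated correlation). ERK feedback and target genes averaged 0.55 (adjusted p = 3.18e-09, and 0.0060 with an estimated correlation). Of them 7 of 10 rose, including Spry2 (1.03) and Phlda1 (0.69), and adjusted over the list alone 8 rose and 1 fell. Immediate-early genes averaged 0.34 (adjusted p = 2.00e-04, and 0.0091 with an estimated correlation) through Egr1 (1.35) and Fos (1.18). In this list 3 of 11 passed, and 4 adjusted over the list alone.

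Cell cycle genes were lower on average, at -0.29 (adjusted p = 3.45e-07, but 0.286 with an estimated correlation). Of 25 tested 6 fell, and 15 adjusted over the list alone. Neural progenitor genes averaged -0.23 (adjusted p = 3.81e-05, and 0.0645 with an estimated correlation). Here 7 of 19 fell, and 10 adjusted over the list alone. Markers of microglia (-0.24, adjusted p = 0.0247, and 0.371 with an estimated correlation), astrocytes (-0.16, adjusted p = 0.0490, and 0.173 with an estimated correlation) and vascular cells (-0.11, adjusted p = 0.0490, and 0.447 with an estimated correlation) were slightly lower, although the phagocyte gene Cd68 rose by 1.04. These calls ended without any of 3, 5 and 5 of the 10 arrays, wild-type 24 h replicates 2 and 5 among them. XBP1-dependent ER genes averaged 0.11 (adjusted p = 0.0092, but 0.447 with an estimated correlation). Of these 6 of 34 rose by either adjustment, Dnajb11 (0.48) most among those kept in every alternative. The joined GABAergic markers averaged 0.33 (adjusted p = 1.29e-04, and 0.122 with an estimated correlation). GABAergic lineage factors, whose mean of 0.0093 and median of -0.04 differed in sign, were not called (adjusted p = 0.863). Glutamatergic genes (-0.11, adjusted p = 0.345) were not called and went both ways, with Slc17a6 up by 0.86 and Fezf2, Eomes and Neurod6 down by changes of -0.57, -0.55 and -0.51. Pan-neuronal genes were not called either (adjusted p = 0.180) and had a mean of 0.17 and a median of -0.07, with Eno2, Nefm and Nefl up by 1.03, 1.02 and 0.98. GABA-A receptor subunits (0.24), neurotrophins and receptors (0.19, with Bdnf itself up by 0.84), ATF4 targets (0.04), cholesterol genes (0.05), oligodendrocyte (-0.03) and erythroid (-0.08) markers and p53 targets (-0.03) did not pass, with adjusted p from 0.208 to 0.844 for these 7 lists. The call for St6gal1 ended with the mean of its probe sets, and without rescaling 275 genes passed in place of 1074.

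**Figure D1:**
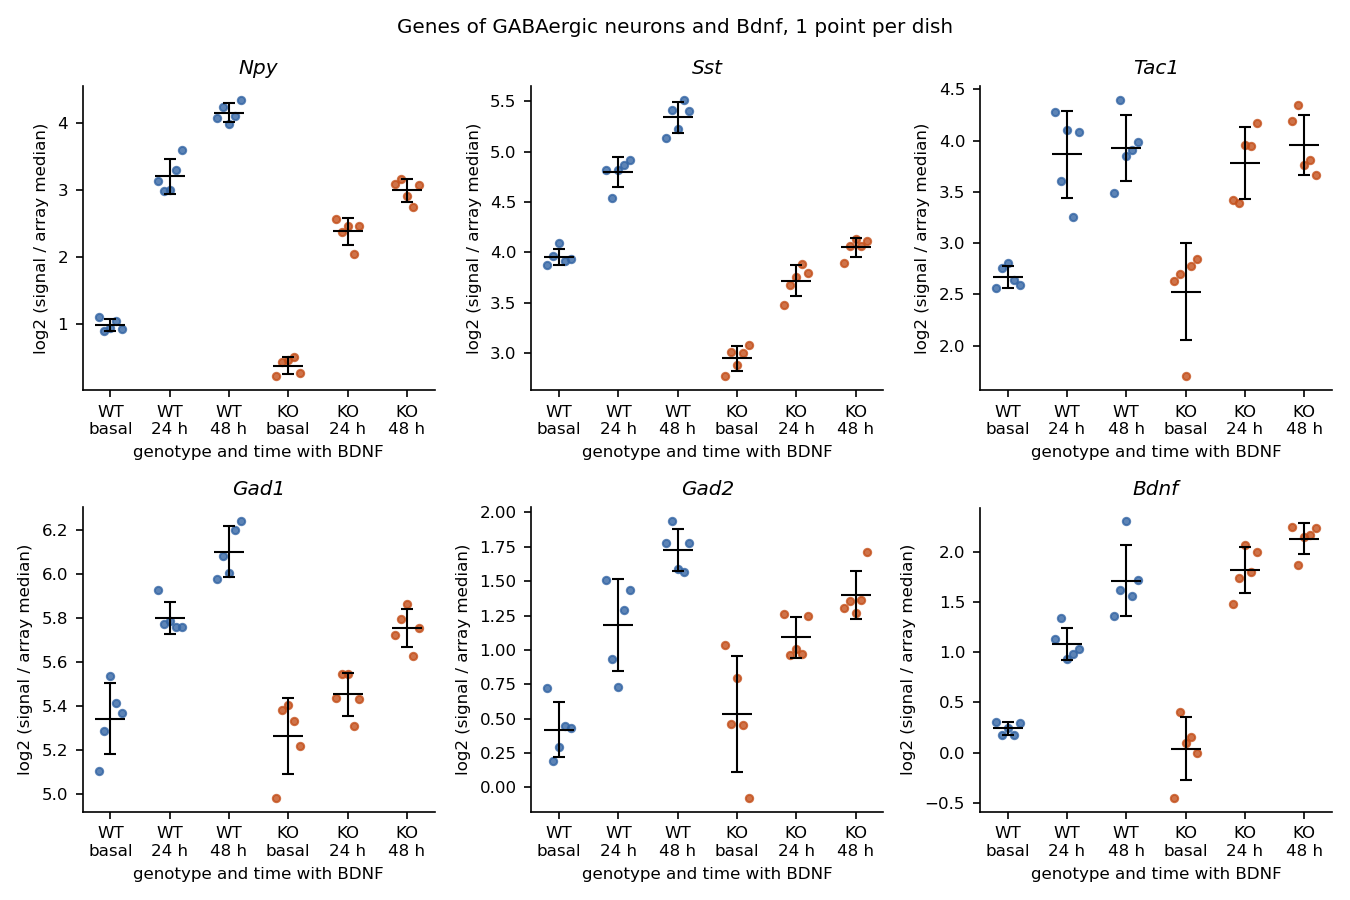
Log2 signal relative to the array median (y) of Npy, Sst, Tac1, Gad1, Gad2 and Bdnf in the 6 groups (x), with 1 point per dish and bars for mean ± SD (n = 5). Npy rose by 2.23 at 24 h and 3.18 at 48 h in wild type, and by 2.02 and 2.63 in the knockout.

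After 48 h in wild type, Npy had risen by 3.18 ± 0.10 (9.06-fold), Pnoc by 2.17 ± 0.09, Sema3e by 2.09 ± 0.16, Cartpt by 1.91 ± 0.12, the pentraxin Nptx1 by 1.89 ± 0.11, Cd68 by 1.87 ± 0.19, Scg2 by 1.76 ± 0.08 and the vasopressin gene Avp by 1.72 ± 0.19 (n = 5). The largest falls were those of the homeobox gene Msx2 (-1.28 ± 0.16), Egfl6 (-1.23 ± 0.15), the retinoic acid binding proteins Crabp2 (-1.17) and Crabp1 (-1.14), Id3 (-1.08), 1600014C10Rik (-1.07), the embryonic globin Hbb-y (-1.03) and Ldb2 (-0.95). These 16 genes kept their calls in the alternatives that tested them; the stricter filter left 9 of them untested and the mean of probe sets 1. Of the tested genes 1524 were higher and 1169 lower, 271 and 157 of them by at least 1.5-fold, and for 1399 the groups did not overlap. The share of called genes that were higher was 56.6%, against 42.7% with quantile normalization, 39.9% with scaling to the 75th percentile and 97.9% without rescaling, so the balance of direction depended on the scaling.

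Secretory granule genes were 1.08 higher on average (13 of 14 rose by either adjustment, the list alone included, Nts by 1.55; adjusted p = 3.27e-15, and 0.0065 with an estimated correlation). Interneuron peptides averaged 0.97 (6 of 8 by either adjustment; adjusted p = 1.96e-05, and 0.0376 with an estimated correlation), with Sst up by 1.38 and Tac1 by 1.26. All 4 tested genes of GABA synthesis rose, Gad2 by 1.31 and Gad1 by 0.76 (list mean 0.75, adjusted p = 5.49e-04, and 0.0376 with an estimated correlation). The 4 GABA-A receptor subunits rose as well, Gabra2 by 1.47 (list mean 0.68, adjusted p = 0.0093, and 0.132 with an estimated correlation). Pan-neuronal genes averaged 0.37 (10 of 19 up and 3 down by either adjustment; adjusted p = 0.0093, and 0.308 with an estimated correlation) with Nefm up by 1.41 and Eno2 by 1.37. Their call also ended with the stricter filter. ERK targets averaged 0.51 (6 up, 1 down by either adjustment; adjusted p = 6.79e-05, and 0.0640 with an estimated correlation), with Dusp6 up by 1.60 and Spry2 by 1.26. ATF4 targets averaged 0.15 (12 of 25 up and 2 down by either adjustment; adjusted p = 0.0373, and 0.412 with an estimated correlation), a call that ended without wild-type 48 h replicate 3 (0.11).

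Lower on average at 48 h in wild type were cell cycle genes (-0.39, 17 of 25 fell and 20 adjusted over the list alone; adjusted p = 1.55e-07, and 0.191 with an estimated correlation) and progenitor genes (-0.32, 11 of 19 by either adjustment, Id1 by -0.81 and Prom1 by -0.68; adjusted p = 3.76e-05, and 0.0726 with an estimated correlation). The 3 tested erythroid genes fell by either adjustment (mean -0.95, adjusted p = 0.0105, and 0.163 with an estimated correlation). Vascular markers averaged -0.23 (adjusted p = 4.97e-04, and 0.132 with an estimated correlation) and GABAergic lineage factors -0.24 (adjusted p = 0.0093, and 0.180 with an estimated correlation), and without rescaling these means turned to 0.085 and 0.069. Immediate-early genes (0.26), p53 targets (-0.12) and the joined GABAergic markers (mean 0.35, median -0.0026) missed the threshold with adjusted p of 0.0533, 0.0533 and 0.0527. Glutamatergic, neurotrophin, XBP1-dependent, cholesterol, astrocyte, oligodendrocyte and microglial lists were not called. With 48 h replicates 1 and 2 alone 1023 genes passed, with a term for replicates 3 to 5 1743, with the Gapdh ratio as a covariate 1470 and without rescaling 4379. With values as deposited the median change of tested genes from basal to 48 h was 0.335 in wild type and 0.293 in the knockout, against 0.023 and 0.045 after scaling.

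Between 24 h and 48 h, wild-type cultures gained the transcripts Snhg11 (1.26 ± 0.25), Qpct (1.02), the astrocyte gene Aldh1l1 (1.01 ± 0.15), Npy (0.95 ± 0.10), Tmem191c (0.95), Gabra2 (0.93), Amy1 (0.91) and Sfswap (0.87). Lower levels were found of Msx2 (-1.09 ± 0.16), Hbb-y (-1.05), Adam4 (-0.92), Ms4a6b (-0.92), Hba-x (-0.89), Srms (-0.87), Crabp2 (-0.86) and Zfp703 (-0.83). In the knockout, Aldh1l1 (0.96 ± 0.15), C1ql3 (0.94), the glycine receptor subunit Glrb (0.89), Gabra2 (0.88), Qpct (0.88), Dock9 (0.77), Tuba4a (0.74) and Mal2 (0.73) rose. The globins Hba-x (-1.68 ± 0.24), Hbb-y (-1.21) and Hbb-bh1 (-1.18) fell, as did Abcb8 (-0.82), Foxm1 (-0.68), Cish (-0.64), Plekhn1 (-0.63) and Gata2 (-0.62). Calls in the alternatives that tested them, which for 13 and 11 of the 16 named genes did not include the stricter filter and for 1 and 4 not the mean of probe sets, were held by Snhg11, Qpct, Aldh1l1, Npy, Tmem191c, Msx2 and Hbb-y in wild type, and by Aldh1l1, Glrb, Dock9, Hba-x, Hbb-y and Hbb-bh1 in the knockout. The counts were 619 higher and 415 lower in wild type and 557 and 175 in the knockout, of which 96 and 53 changed at least 1.5-fold. Groups did not overlap for 480 and 442. The share higher was 59.9% and 76.1%, against 45.0% and 52.5% with quantile normalization, 40.6% and 46.0% with scaling to the 75th percentile and 99.5% and 99.3% without rescaling. With 48 h replicates 1 and 2 alone, only 136 and 181 genes passed. A term for 48 h replicates 3 to 5 gave 383 and 157, and the Gapdh ratio as a covariate 294 and 55. Without wild-type 48 h replicate 3 the wild-type count was 594, and the knockout count was 348 and 419 without knockout 48 h replicates 3 and 5 and 462 and 407 without 24 h replicates 1 and 4.

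Of the lists, the 3 tested erythroid genes fell between 24 h and 48 h in both genotypes by either adjustment, by -0.88 in wild type (adjusted p = 0.0032, and 0.177 with an estimated correlation) and -1.35 in the knockout (adjusted p = 2.89e-07, and 0.0188 with an estimated correlation). Secretory granule genes averaged 0.21 (6 of 14, and 7 adjusted over the list alone; adjusted p = 0.0043, and 0.277 with an estimated correlation) and 0.24 (5, and 6 adjusted over the list alone; adjusted p = 0.0040, and 0.252 with an estimated correlation). GABA-A subunits averaged 0.44 (adjusted p = 0.0109, and 0.177 with an estimated correlation) and 0.46 (adjusted p = 0.0113, and 0.178 with an estimated correlation). Wild type also showed higher pan-neuronal genes (0.21, Snap25 up by 0.54), GABA synthesis genes (0.31), interneuron peptides (0.26, Sst up by 0.54) and ATF4 targets (0.11), and lower lineage factors (-0.25), vascular markers (-0.11), p53 targets (-0.09) and cell cycle genes (-0.09). Adjusted p ranged from 0.0023 to 0.0342 and from 0.177 to 0.728 with an estimated correlation for these 8 lists. The last 4 means turned positive without rescaling. Without wild-type 24 h replicate 2 the calls for GABA synthesis (0.27), peptides (0.22) and p53 targets (-0.10) ended and the cell cycle mean turned to 0.0085. Without 48 h replicate 3 that for ATF4 targets (0.07) ended. The knockout showed higher cholesterol genes (0.15, adjusted p = 0.0162, and 0.252 with an estimated correlation) and astrocyte markers (0.28, adjusted p = 0.0210, and 0.178 with an estimated correlation), calls that ended without knockout 48 h replicate 2 (0.15 and 0.26).

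Knockout cultures were tested in the same way. After 24 h of BDNF, Npy rose by 2.02 ± 0.10, Scg2 by 1.85 ± 0.08, Nptx1 by 1.82 ± 0.11, Sema3e by 1.81 ± 0.16, Bdnf itself by 1.78 ± 0.14, Pnoc by 1.56 ± 0.09, Dlk1 by 1.54 ± 0.13 and the neurotensin gene Nts by 1.49 ± 0.11 (n = 5). Recql5 (-0.77), Sla (-0.71), Palmd (-0.69), Id2 (-0.67), Serping1 (-0.66), Oas1c (-0.66), the matrix gene Fmod (-0.65) and Tmem98 (-0.62) fell most; the calls for Serping1 and Tmem98 ended without rescaling, and that of Tmem98 also without knockout 24 h replicate 4 (-0.57) or 5 (-0.49). In all 443 genes were higher and 413 lower, 79 and 17 by at least 1.5-fold, and for 512 the groups did not overlap. The share higher was 51.8%, against 47.7% with quantile normalization, 43.0% with scaling to the 75th percentile and 90.0% without rescaling. Array weights gave 1584 genes in place of 856, values as deposited gave 201, and leaving out knockout 24 h replicate 2 gave 561.

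Secretory granule genes averaged 0.93 in the knockout at 24 h (12 of 14 rose, and 13 adjusted over the list alone; adjusted p = 8.97e-25, and 3.15e-04 with an estimated correlation). Interneuron peptides averaged 0.74 (6 of 8 by either adjustment, Tac1 by 1.251, Calb1 by 1.09 and Sst by 0.77; adjusted p = 3.22e-10, and 0.0023 with an estimated correlation). ERK targets averaged 0.31 (6 up and 1 down, 2 down adjusted over the list alone; adjusted p = 1.92e-05, and 0.0502 with an estimated correlation), with Dusp6 up by 0.82 and Spry2 by 0.39, a call that the mean of Spry2 probe sets ended. Immediate-early genes averaged 0.26 (4 up and 2 down by either adjustment, Egr1 by 1.14; adjusted p = 0.0056, and 0.0502 with an estimated correlation). Pan-neuronal genes averaged 0.19 (adjusted p = 0.0175, and 0.319 with an estimated correlation) with Nefm up by 1.14. Genes of GABA synthesis averaged 0.27 and missed the threshold (adjusted p = 0.0506), although Gad2 rose by 0.56, a call that ended without knockout basal replicate 5 (0.40). The joined GABAergic markers averaged 0.28 (adjusted p = 3.50e-04, and 0.165 with an estimated correlation). Cell cycle (-0.23, adjusted p = 1.08e-05, and 0.279 with an estimated correlation), progenitor (-0.22, adjusted p = 8.95e-05, and 0.0984 with an estimated correlation) and vascular genes (-0.12, adjusted p = 0.0200, and 0.279 with an estimated correlation) were lower, the last not without knockout basal replicate 5 (-0.08). XBP1-dependent genes (0.04, adjusted p = 0.395) and the remaining 11 lists were not called.

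After 48 h in the knockout, Npy rose by 2.63 ± 0.10 (6.19-fold), Bdnf by 2.09 ± 0.14, Sema3e by 2.02 ± 0.16, Nts by 2.00 ± 0.11, Scg2 by 1.97 ± 0.08, Nptx1 by 1.94 ± 0.11, Cartpt by 1.80 ± 0.12 and the tachykinin receptor Tacr3 by 1.78 ± 0.15 (n = 5). Hba-x (-1.16 ± 0.24), Abcb8 (-0.92), Zfp185 (-0.92), the interferon-induced gene Ifit1 (-0.87), Crabp2 (-0.81), Sez6l (-0.80) and the contractile genes Tpm2 (-0.79) and Myl9 (-0.76) fell most, and Abcb8 lost its call with the mean of its probe sets. In all 1443 genes were higher and 704 lower, 213 and 51 by at least 1.5-fold, and for 1285 the groups did not overlap. The share higher was 67.2%, against 47.6% with quantile normalization, 41.5% with scaling to the 75th percentile and 98.8% without rescaling. The count was 1193 with 48 h replicates 1 and 2 alone, 992 with the Gapdh covariate and 3732 without rescaling.

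Secretory granule genes averaged 1.17 at 48 h in the knockout (13 of 14 by either adjustment, Pnoc by 1.70; adjusted p = 3.73e-19, and 0.0017 with an estimated correlation). Interneuron peptides averaged 0.92 (7 of 8 by either adjustment, Tac1 by 1.43 and Sst by 1.10; adjusted p = 6.15e-07, and 0.0173 with an estimated correlation). GABA synthesis genes averaged 0.53 (3 of 4, and 4 adjusted over the list alone, Gad2 by 0.87 and Gad1 by 0.49; adjusted p = 0.0057, and 0.0740 with an estimated correlation). GABA-A subunits averaged 0.72 (4 of 4, Gabra2 by 1.36; adjusted p = 0.0037, and 0.0740 with an estimated correlation). Cholesterol synthesis genes averaged 0.23 (11 of 18 up and 1 down by either adjustment, Pmvk by 0.50; adjusted p = 0.0037, and 0.126 with an estimated correlation). ERK targets averaged 0.32 (adjusted p = 0.0047, and 0.155 with an estimated correlation), pan-neuronal genes 0.30 (adjusted p = 0.0307, and 0.454 with an estimated correlation) and the joined GABAergic markers 0.36 (adjusted p = 0.0184, and 0.333 with an estimated correlation). Erythroid genes averaged -0.95 (3 of 3, adjusted p = 0.0043, and 0.126 with an estimated correlation). Lower means were also found for progenitor genes (-0.16, adjusted p = 0.0037, and 0.166 with an estimated correlation), p53 targets (-0.13, adjusted p = 0.0071, and 0.0520 with an estimated correlation), vascular markers (-0.08, adjusted p = 0.0087, and 0.284 with an estimated correlation) and lineage factors (-0.12, adjusted p = 0.0300, and 0.302 with an estimated correlation), and these 4 turned positive without rescaling. The lineage factor call ended without knockout basal replicate 2 (-0.10) or 4 (-0.08), and the pan-neuronal call without knockout basal (0.30) or 48 h (0.27) replicate 5. Other lists, among them XBP1-dependent genes (0.08, adjusted p = 0.697), were not called. Microglial and astrocyte means were 0.07 and 0.13 but their medians -0.11 and -0.12.

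**Figure D2:**
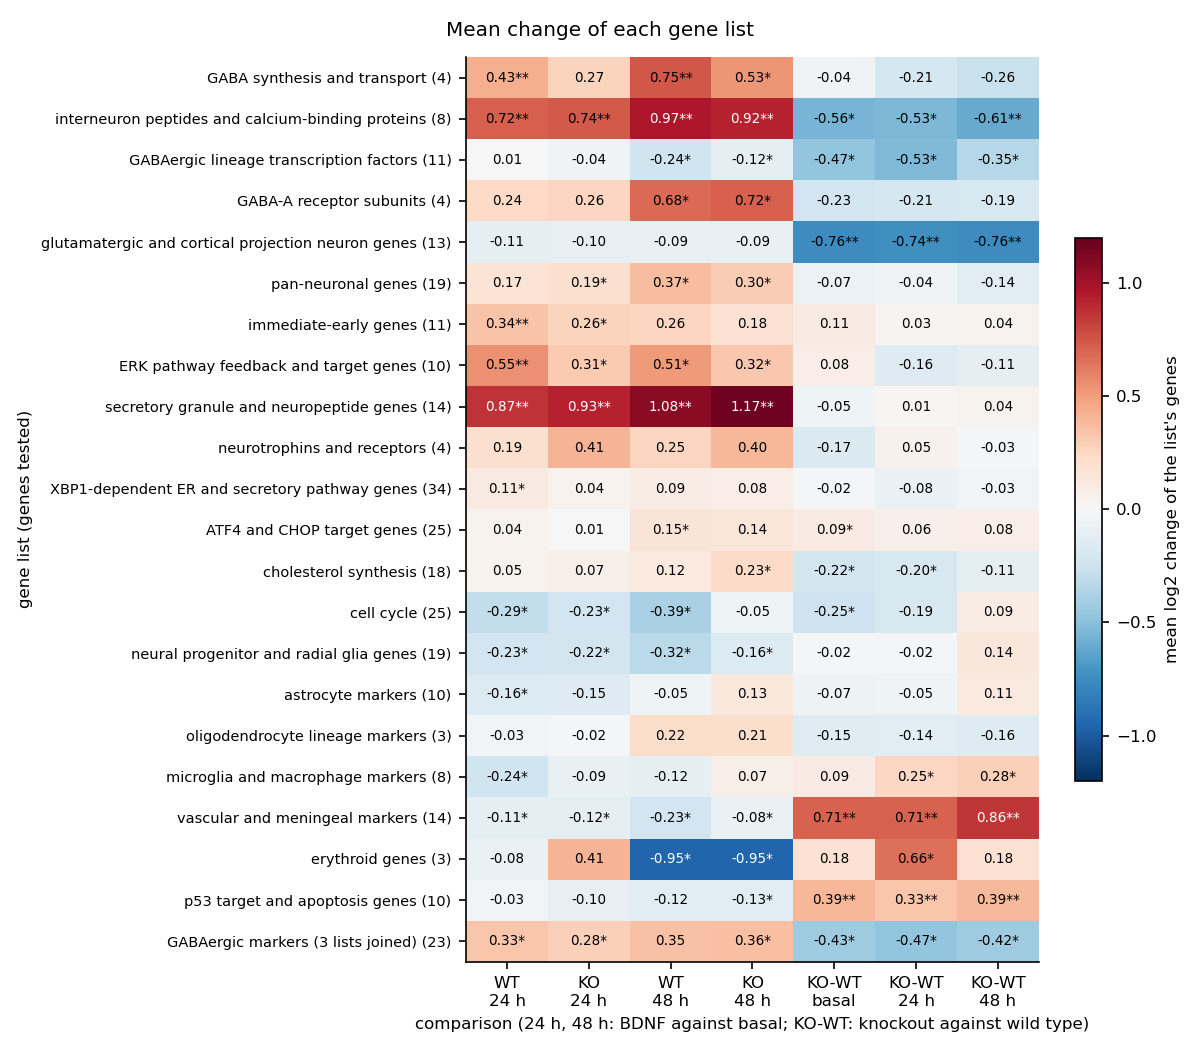
Mean log2 difference of each gene list (vertical, number of tested genes in brackets) in each comparison (horizontal), coloured by size; 1 star marks an adjusted camera p under 0.05, a pair of stars one that also holds with an estimated correlation. Secretory granule genes averaged 0.87, 1.08, 0.93 and 1.17 in the 4 BDNF comparisons against basal.

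The comparison of genotypes asked what differs between cultures from knockout and wild-type embryos. Without BDNF, the largest difference was in sex-linked genes: Xist, transcribed from the inactive X, was 6.08 ± 0.15 higher in the knockout and the Y-linked Eif2s3y lower (-6.04). For Eif2s3y 6 of 15 knockout arrays lay at the floor, so its differences are bounds. The pools therefore differed in the sex of their embryos. Genes active in dopaminergic and floor plate cells, Slc6a3 (2.53 ± 0.19) and Foxa1 (2.52 ± 0.22), were higher in the knockout, as were the connective tissue genes Epyc (2.35), Tnmd (2.29), Dkk2 (2.29), Fmod (2.23) and Egfl6 (2.13). Genes of choroid plexus and epithelium, Ttr (-3.56 ± 0.46), Folr1 (-2.30 ± 0.15) and Krt8 (-2.18), were lower, as were Clu (-1.58), the cortical neuron genes Fezf2 (-1.47 ± 0.12) and Neurod6 (-1.38 ± 0.11), and Slc15a2 (-1.39). Ttr read 7.14 ± 0.07 in wild type and 3.58 ± 1.55 in the knockout (SD, n = 5), so knockout dishes varied widely. Of the tested genes 684 were higher and 1389 lower, 317 and 150 by at least 1.5-fold, and for 1286 the groups did not overlap.

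With BDNF present, at 24 h Xist (6.01), Egfl6 (2.61), Slc6a3 (2.58), Foxa1 (2.56), Tal1 (2.32), Epyc (2.30), Tnmd (2.22) and Foxd1 (2.02) were higher and Eif2s3y (-5.92), Ttr (-3.90), Krt8 (-2.14), Folr1 (-1.88), Dlx1as (-1.59), C1ql3 (-1.45), Slc15a2 (-1.43) and Neurod6 (-1.40) lower. At 48 h Xist (6.26), Slc6a3 (3.39), Egfl6 (2.94), Epyc (2.81), Foxa1 (2.55), Dkk2 (2.29), Id3 (2.18) and Tnmd (2.16) were higher and Eif2s3y (-6.11), Ttr (-2.58), Krt8 (-2.07), Folr1 (-1.90), Neurod2 (-1.66), Tcim (-1.65), Fezf2 (-1.41) and C1ql3 (-1.31) lower. The counts were 627 higher and 1322 lower at 24 h and 720 and 1071 at 48 h, of which 298 and 135 and then 371 and 114 differed at least 1.5-fold. Groups did not overlap for 1213 and 1134. At all 3 times 495 genes were higher and 509 lower. The genes named from each time kept their calls in the alternatives that tested them. The stricter filter left 9, 10 and 10 of the 16 untested, the mean of probe sets 1, and exclusion of genes on X and Y 4. The share of called genes that were higher was 33.0%, 32.2% and 40.2% at the 3 times, against 46.7%, 51.4% and 53.2% with quantile normalization and 46.3%, 47.4% and 49.8% with scaling to the 75th percentile. Without rescaling 842, 877 and 882 genes passed, of which 73.4%, 83.4% and 65.4% were higher, so the balance of direction turned with the scaling.

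**Figure D3:**
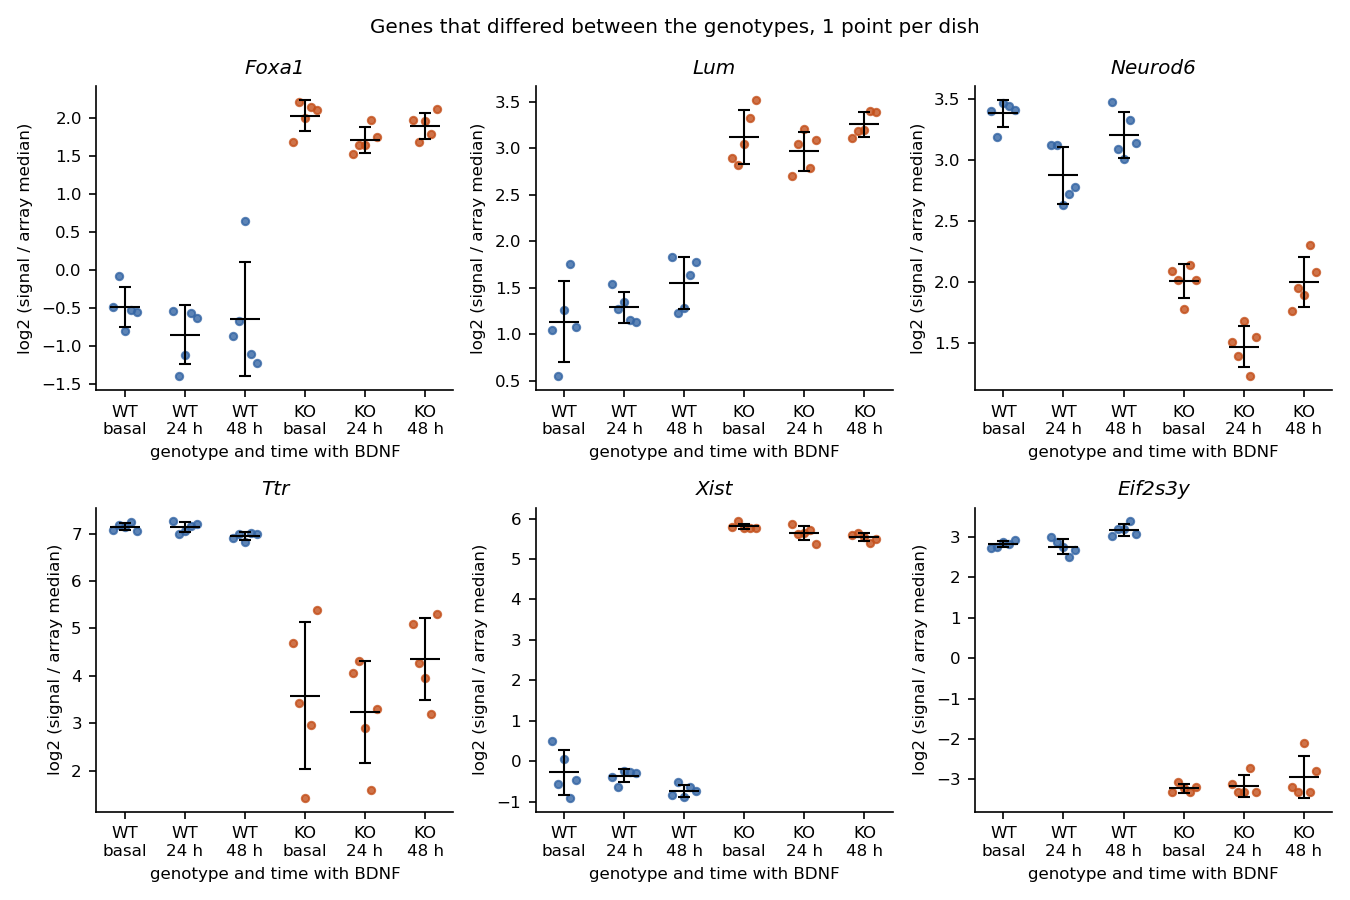
Log2 signal relative to the array median (y) of Foxa1, Lum, Neurod6, Ttr, Xist and Eif2s3y in the 6 groups (x), with 1 point per dish and bars for mean ± SD (n = 5). Basal knockout minus wild-type differences were 2.52, 1.99, -1.38, -3.56, 6.08 and -6.04.

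Glutamatergic and cortical projection neuron genes were lower in the knockout by mean differences of -0.76, -0.74 and -0.76 without BDNF, at 24 h and at 48 h (11, 10 and 10 of 13 were lower, and 11, 11 and 10 adjusted over the list alone, while up to 2 were higher; adjusted p = 7.15e-06, 4.35e-06 and 6.36e-07, and 0.0069, 0.0066 and 0.0029 with an estimated correlation). In basal dishes Gria1 differed by -1.12. Vascular and meningeal markers were higher by 0.71, 0.71 and 0.86 (12, 12 and 13 of 14 by either adjustment, while 1 was lower, or 2 without BDNF adjusted over the list alone; adjusted p = 3.59e-16, 5.73e-18 and 6.28e-20, and 0.0011, 0.0011 and 5.81e-04 with an estimated correlation). Among them were the collagen-binding genes Lum (1.99) and Dcn (1.41) and the pericyte receptor Pdgfrb (1.14) in basal dishes. The p53 target and apoptosis genes were higher by 0.39, 0.33 and 0.39 (7, 5 and 6 of 10 were higher, and 7, 6 and 6 adjusted over the list alone; adjusted p = 7.15e-06, 1.44e-05 and 6.47e-06, and 0.0011, 0.0011 and 6.49e-04 with an estimated correlation). Pmaip1 (1.61) and Cdkn1a (0.58) were among them in basal dishes. These 3 lists kept their calls in every alternative.

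The 3 GABAergic lists did not all differ between genotypes. Interneuron peptides and calcium-binding proteins differed by -0.56, -0.53 and -0.61 (5 of 8 at each time, and 6, 5 and 5 adjusted over the list alone; adjusted p = 2.05e-04, 3.26e-04 and 3.96e-05, and 0.0735, 0.0691 and 0.0419 with an estimated correlation). Basal differences were -1.01 for Sst, -0.95 for Reln, -0.92 for Calb1 and -0.61 for Npy. GABAergic lineage transcription factors differed by -0.47, -0.53 and -0.35 (8 of 11 at each time by either adjustment, with up to 3 higher; adjusted p = 0.0053, 4.58e-04 and 0.0375, and 0.210, 0.0956 and 0.457 with an estimated correlation). Basal Lhx6 differed by -0.95 and Dlx2 by -0.91, and the call at 48 h ended without wild-type 48 h replicate 4 (-0.32). The joined list differed by -0.43, -0.47 and -0.42 (adjusted p = 8.64e-05, 2.53e-06 and 1.32e-05, and 0.140, 0.0637 and 0.0881 with an estimated correlation). Genes of GABA synthesis were not called as a list (-0.04, -0.21 and -0.26, adjusted p of camera = 0.943, 0.368 and 0.20). Among its members limma called Gad1 lower in the knockout at 24 h (-0.35, adjusted p = 5.63e-04) and at 48 h (-0.35, adjusted p = 4.88e-04). It also called Slc32a1 lower without BDNF (-0.28, adjusted p = 0.0478) and at 48 h (-0.34, adjusted p = 0.0155). The sign for Slc32a1 at 48 h turned with the mean of its probe sets. Gad2 and Abat did not pass at any time. XBP1-dependent ER and secretory pathway genes were not called as a list (-0.0165, -0.08 and -0.03; adjusted p = 0.421, 0.759 and 0.844). In basal dishes 4 of 34 were higher and 5 lower by either adjustment, with Sec24d (0.56) and Pdia5 (0.44) among the former and Wfs1 (-0.57) and Sdf2l1 (-0.38) among the latter. At 24 h 3 were higher and 8 lower (9 lower adjusted over the list alone), among them Pdia5 (0.46), Sec31a (0.34), Sdf2l1 (-0.49) and Dnajb9 (-0.38). At 48 h Sec24d (0.40) was higher and Dnajb9 (-0.52), Sec61b (-0.36) and Edem1 (-0.29) lower, 2 of these 3 adjusted over the list alone.

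Cholesterol genes were lower without BDNF and at 24 h (-0.22 and -0.20, adjusted p = 0.0072 and 0.0190, and 0.210 and 0.304 with an estimated correlation). Weak calls that also ended in other alternatives were those of ATF4 targets (0.09, adjusted p = 0.0389, and 0.711 with an estimated correlation) and cell cycle genes (-0.25, adjusted p = 0.0432, and 0.718 with an estimated correlation) without BDNF, erythroid genes at 24 h (0.66, adjusted p = 0.0451, and 0.352 with an estimated correlation) and microglial markers at 24 h and 48 h (0.25 and 0.28, adjusted p = 0.0311 and 0.0341, and 0.413 and 0.457 with an estimated correlation). These calls ended without any of 2, 4, 6, 5 and 3 of the 10 arrays, in that order. Pan-neuronal genes were not called (-0.07, -0.04 and -0.14). The remaining lists were not called at any of the 3 times. Of 242 list results in all 11 comparisons, mean, median and test differed in sign in 41, and 0 of these were called by camera. Genotype had 1 pool each, so no spread between pools was measured.

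Genes whose response to BDNF differed between genotypes were few. At 24 h limma called 7 genes, with 455 at an unadjusted p under 0.05. The share higher was 28.6%, against 53.8% of 13 with quantile normalization and 41.7% of 12 with scaling to the 75th percentile. The ERK phosphatase Dusp6 rose by 1.49 in wild type and 0.82 in the knockout, a difference of -0.67 ± 0.11 (adjusted p = 0.0059), and the ERK inhibitor Spry2 by 1.03 and 0.39, a difference of -0.64 ± 0.13 (adjusted p = 0.0162). Igf1 (-0.58 ± 0.10, adjusted p = 0.0059), the protease gene Adamts5 (-0.74 ± 0.14, adjusted p = 0.0126) and the synaptic scaffold gene Homer2 (-0.54 ± 0.10, adjusted p = 0.0162) also changed more negatively in the knockout. Bdnf rose by 0.84 in wild type and 1.78 in the knockout (0.93 ± 0.19, adjusted p = 0.0367), and Zcchc18 differed by 0.60 ± 0.12 (adjusted p = 0.0162). The Bdnf call was lost without any of 13 of the 20 arrays, the Zcchc18 call without wild-type basal replicate 2 (0.54) or 3 (0.58) or knockout 24 h replicate 3 (0.57), and those of Spry2 (-0.61) and Homer2 (-0.51) without wild-type basal replicate 3, while Dusp6, Igf1 and Adamts5 kept theirs in each omission. The count was 3 without wild-type basal replicate 3, 16 without wild-type basal replicate 4 and 11 without knockout 24 h replicate 2, and without rescaling limma called 0 genes. ERK feedback and target genes as a list responded less in the knockout, with a mean difference of -0.23 (adjusted p = 2.58e-05, but 0.115 with an estimated correlation); 2 of 10 passed, and 3 adjusted over the list alone. No other list was called.

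At 48 h limma called 10 genes, with 515 at an unadjusted p under 0.05. The share higher was 50% of 10, and 20% of 10 with scaling to the 75th percentile. The proprotein convertase Pcsk5 (-0.83 ± 0.13, adjusted p = 0.0026) and Igf1 (-0.54 ± 0.10, adjusted p = 0.0163) had lower responses in the knockout and kept their calls whichever array was left out. Igfbp4 (-0.75 ± 0.15), Dusp6 (-0.55 ± 0.11) and Slit2 (-0.47 ± 0.10) were also lower, and Ndrg2 (0.89 ± 0.19), Pcsk1 (0.84 ± 0.17), Igfbp7 (0.81 ± 0.18), Id3 (0.76 ± 0.16) and Clu (0.63 ± 0.13) higher, with adjusted p from 0.0354 to 0.0490; these calls were lost without any of 11 (Clu) to 19 (Slit2) of the 20 arrays. The count ranged from 2 to 13 as each array was left out, and it was 1 with 48 h replicates 1 and 2 alone and 0 without rescaling. ERK targets averaged lower here too (-0.19, adjusted p = 5.96e-05, but 0.184 with an estimated correlation). Of these 1 of 10 passed, and 2 adjusted over the list alone. The differences at 24 h and 48 h share the basal arrays, so the later one is not an independent repeat. The cell cycle list had a more positive mean response in the knockout (0.34, adjusted p = 3.28e-10), but 0 of 25 members passed by either adjustment and the call was lost with an estimated correlation (adjusted p = 0.293). Responses were also more positive for progenitor (0.16, adjusted p = 0.0166, and 0.293 with an estimated correlation), astrocyte (0.18, adjusted p = 0.0191, and 0.209 with an estimated correlation), cholesterol (0.11, adjusted p = 0.0191, and 0.293 with an estimated correlation) and vascular genes (0.15, adjusted p = 0.0319, and 0.477 with an estimated correlation). Of these, progenitor calls ended without wild-type basal replicate 4 (0.12) or 48 h replicate 5 (0.16), the astrocyte call without knockout 48 h replicate 2 (0.16), the cholesterol call without wild-type basal replicate 2 (0.09) and the vascular call without any of 8 arrays.

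**Figure D4:**
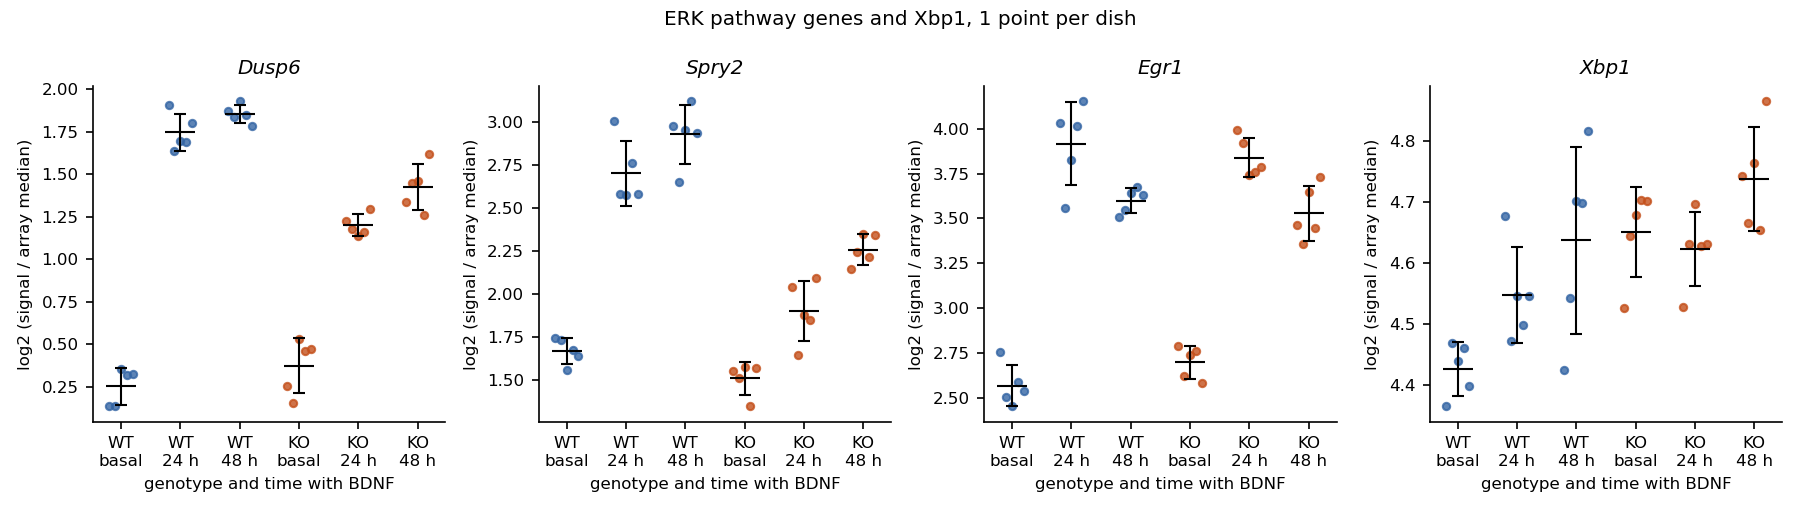
Log2 signal relative to the array median (y) of Dusp6, Spry2, Egr1 and Xbp1 in the 6 groups (x), with 1 point per dish and bars for mean ± SD (n = 5). Dusp6 rose by 1.49 in wild type and 0.82 in the knockout at 24 h.

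The series title concerns GABAergic markers, so their response was compared between genotypes. The response of the joined list did not differ past the threshold, with a mean difference of -0.046 at 24 h (adjusted p = 0.509, and 0.842 with an estimated correlation) and 0.0065 at 48 h (adjusted p = 0.576, and 0.835 with an estimated correlation), whose sign turned to -0.0111 with scaling to the 75th percentile. Genes of GABA synthesis and transport responded less at 48 h, by -0.22 (adjusted p = 0.0191, but 0.209 with an estimated correlation). Of 4 genes 0 passed, and 0 adjusted over the list alone, and the call also ended without wild-type 48 h replicate 5 (-0.18). At 24 h the list differed by -0.17 (adjusted p = 0.213). Gad1 differed by -0.27 ± 0.10 at both times (adjusted p = 0.586 and 0.528), Gad2 by -0.20 and -0.44 ± 0.21, Abat by -0.29 and -0.09 and Slc32a1 by 0.08 and -0.07. Of the peptide genes, Npy differed by -0.21 ± 0.15 and -0.55 ± 0.15 (adjusted p = 0.936 and 0.185), Sst by -0.07 and -0.28, and Tac1 by 0.05 and 0.17. Reln differed by 0.34 ± 0.11 and 0.41 ± 0.11 (adjusted p = 0.415 and 0.194), Calb1 by -0.03 and 0.06, Calb2 by -0.06 and -0.01, Cck by 0.15 and 0.06 and Nxph1 by 0.02 and -0.25. The values for Calb1, Calb2 at 24 h and Cck at 48 h changed sign without rescaling. Over all genes, 0 of these 12 passed in limma, with unadjusted p under 0.05 for 2 at 24 h and 5 at 48 h. Adjusted over the peptide list alone, Reln was higher at 24 h, and at 48 h Reln was higher and Npy and Sst lower. Adjusted over these 12 genes, only Npy and Reln at 48 h passed in limma (adjusted p = 0.0051 for each). Reln at 24 h (adjusted p = 0.0582) and Sst at 48 h (adjusted p = 0.0538) then did not. The peptide list itself was not called (0.02 and -0.05, adjusted p of camera = 0.730 and 0.407). Peptide genes left out by the filter went both ways between genotypes. Mean Vip signals at basal, 24 h and 48 h were -2.10, -0.73 and 0.07 in wild type. In the knockout they were higher, at -1.35, 0.04 and 0.82. Cort was lower in the knockout, at -2.50, -1.52 and -2.06 against -1.64, -0.92 and -0.40. Both genes were picked after their values were seen and were not tested.

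Across the 7436 tested genes, the change from basal in knockout cultures with BDNF followed that in wild type. The correlation across genes of log2 changes was r = 0.716 (rho = 0.649) at 24 h and r = 0.833 (rho = 0.803) at 48 h; genes are not independent replicates. Without the filter on low genes it was 0.454 and 0.675. Of the genes called in wild type, 1015 of 1074 at 24 h and 2599 of 2693 at 48 h had a log2 change of the same sign in the knockout, past the threshold or not. At 24 h 266 genes were called higher in both genotypes, where independence gives 35.6, and 206 lower, where it gives 26.4. At 48 h these counts were 1056 and 511, against 296 and 111. Both genotypes at 48 h also shared a later day in vitro and lower Gapdh 3'/5' ratios than basal dishes. These shared differences can raise the correlation and the overlap at 48 h apart from BDNF. Among genes called in either genotype, the principal-axis slope of knockout on wild-type change was 0.894 at 24 h and 0.836 at 48 h, with Npy, Pnoc, Sema3e and Scg2 at the upper end in both.

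**Figure D5:**
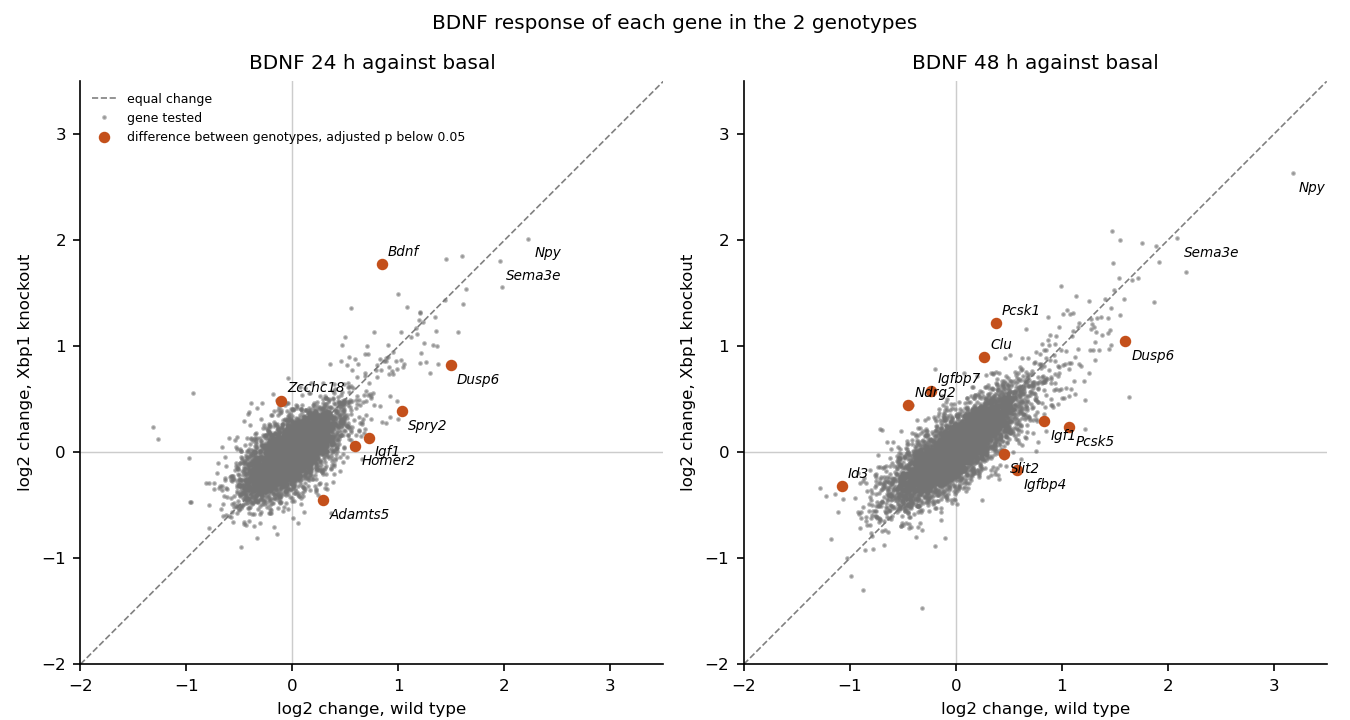
Log2 change of each tested gene in wild type (x) and knockout (y) after 24 h and 48 h of BDNF; the dashed line marks equal change and orange points the 7 and 10 genes whose response differed between genotypes. The correlation across genes was 0.716 and 0.833.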

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

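Tests chosen only after the result was seen were those of the sex of the pools, of fewer neurons (whose criterion was rewritten), of the loss of XBP1, of array scaling for ERK genes and of a smaller response of all genes at 48 h. The tissues of the lists for other tissue were chosen with genes of large genotype differences already seen.

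Knockout and wild-type arrays differed in 1004 genes in 1 direction at all 3 times. Genes on X or Y make up little of this set, at 3.8% of it (3.24% of tested genes lie there). Effects of sex on genes of other chromosomes were not tested, and sex cannot be told apart from genotype because the pools differed in both. Markers of other cell types moved apart by 0.777, from -0.07 ± 0.27 for astrocytes to 0.71 ± 0.20 (SEM) for vascular and meningeal cells. Fewer neurons with all other cell types raised alike would not give this. Fewer neurons with only some of these raised could, so a lower share of neurons stays open. Other tissue in the knockout pool is a candidate explanation. All 3 lists written for this test were higher at all times, with an estimated correlation as well. Midbrain, diencephalon and floor plate genes differed by 0.84, 0.96 and 0.93 (12 tested, of which 9, 8 and 8 were higher and 0, 0 and 1 lower). Mesenchymal genes differed by 0.88, 0.80 and 0.92 (20 tested, 18 higher and 2 lower, Postn and Thy1, at each time, and 3 of the full list also in a fixed list). Choroid plexus genes differed by 0.59, 0.53 and 0.77 (6 tested, of which 5, 5 and 6 were higher and 0 lower). The choroid plexus genes Ttr and Folr1, left out because they had been seen, were lower, so for this tissue the test decides nothing. Genes of these tissues had been seen to differ in the same arrays before the lists were written. The lists are therefore not independent support for other tissue. Telencephalon identity genes, 12 of 24 of them in a fixed list and 15 tested, had mean differences of -0.76, -0.76 and -0.72 (12, 13 and 13 lower, and Six3 higher at 24 h; adjusted p with an estimated correlation at most 3.03e-04). Loss of XBP1, with a mean of -0.0165 over XBP1-dependent genes that went both ways without BDNF, while Dnajb9 was lower at 24 h and 48 h (-0.38 and -0.52), cannot be told apart from a difference between pools, because each genotype was 1 pool.

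In both genotypes the 48 h replicates 1 and 2 stood apart from 48 h replicates 3 to 5 in the ratio of the 75th percentile to the median signal (at most 4.24 against at least 4.47 in wild type, and 4.17 against 4.38 in the knockout). On the second principal component knockout replicate 4 (11.2) lay beside replicates 1 and 2 (10.7 and 11.2), so the split was not clean there. The difference correlated across genes between genotypes (r = 0.304). RNA quality or labelling stays open. The difference did not follow the slope on the Gapdh 3'/5' ratio within basal and 24 h arrays (r = -0.0108 across genes; the slopes themselves correlated between genotypes with r = 0.393), but those arrays spanned ratios of 2.57 to 3.05 and 8 of the 10 arrays at 48 h lay below that range. The bound written for this test did not allow for that, a limit noted only after the result was seen. Replicates 3 to 5 had lower mean ratios than replicates 1 and 2, at 2.44 against 2.53 in wild type and 2.27 against 2.59 in the knockout, and higher means of the median signal (122 against 115 and 127 against 115). Single arrays overlapped in the ratio in wild type and in the median signal in both genotypes. Cultures at a later stage of the response stay open with r = 0.11 to the change from basal to 24 h, and cannot be told apart from a difference in handling, because the labels give no batch or day for single dishes. The condition that the slopes be reproducible was added after the first correlation had been seen. No other biological explanation was tested.

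The list of ERK feedback and target genes had a lower mean response in the knockout at both times, which share the basal arrays, with the preset correlation. Its call ended with an estimated correlation (adjusted p = 0.115 and 0.184). Under quantile or 75th percentile scaling, the highest adjusted p of camera with the preset correlation was 2.76e-04. Camera compares the list with all other genes, so a factor common to an array largely cancels. Scaling to the 75th percentile could therefore hardly change the call. With the preset correlation the call held under quantile normalization, while an effect of scaling on the mean itself was not tested. A smaller response of all genes was tested with random sets of genes of like response. Of these sets 99.9% lay above the list at 24 h (mean -0.23, random median -0.017) and 99.2% at 48 h (mean -0.19, random median -0.021). The typical set thus showed little of the list's difference. Genes of the sets were drawn independently, without the correlation between list members, so these shares are too high. A smaller response of all genes is therefore not excluded. Less mRNA of the BDNF receptor gene Ntrk2 stays open, as 1 probe set of Ntrk2 was lower past the threshold only at 24 h (-0.25, adjusted p = 0.0307) and not without BDNF (-0.14, adjusted p = 0.269) or at 48 h (-0.20, adjusted p = 0.106). The other, near the floor, differed by up to 0.384, with the opposite sign without BDNF and at 24 h, and never passed. Less Ntrk2 mRNA therefore cannot be told apart from an unrelated difference as a source of the pattern. A weaker ERK signal in the knockout was not tested.

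For the 9 comparisons of groups, 100 splits of the same arrays were counted. As many genes came only from the real split (1) or, at 24 h in the knockout, from 1 more (2). A random assignment of dishes to groups thus seldom gave such counts. The splits exchange dishes of 1 pool per genotype, so they say nothing about chance differences between pools. In wild type the real counts were 1074 at 24 h, 2693 at 48 h and 1034 between them, and the highest others 229, 1396 and 672. In the knockout they were 856, 2147 and 732 against 938, 582 and 17, and between genotypes 2073, 1949 and 1791 against 653, 568 and 1121. For the genotype difference in response, residuals of the additive model were reassigned among arrays in place of splits. The counts were 7 and 10 against 5 and 163, and 1 and 2 of 100 were as large, the real one included. Counts as large were rare among these reassignments, which does not exclude chance for single genes. The 48 h count ranged from 2 to 13 as each array was left out. A single reassignment gave 163 genes, many times the real count, while the median of the reassignments was 0. Its source was not tested. The split with 938 genes exchanged knockout 24 h replicate 1 with knockout basal replicate 5; Npy read 2.56 and 0.25 in these, near their own groups.

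Differences in BDNF response between genotypes, found by limma, were seen for 7 genes at 24 h and 10 at 48 h. At 24 h they were Adamts5 (-0.74), Bdnf (0.93), Dusp6 (-0.67), Homer2 (-0.54), Igf1 (-0.58), Spry2 (-0.64) and Zcchc18 (0.60). At 48 h they were Clu (0.63), Dusp6 (-0.55), Id3 (0.76), Igf1 (-0.54), Igfbp4 (-0.75), Igfbp7 (0.81), Ndrg2 (0.89), Pcsk1 (0.84), Pcsk5 (-0.83) and Slit2 (-0.47). Lists found by camera were ERK targets at 24 h (-0.23) and 48 h (-0.19) and, at 48 h, GABA synthesis (-0.22), cholesterol synthesis (0.11), cell cycle (0.34), progenitor genes (0.16), astrocyte (0.18) and vascular markers (0.15); 0 of these calls held with an estimated correlation.

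An array stood apart from the 4 others of its group in 23 of 240 groups of the reported measures and in 93 of 1560 groups of named genes (5.96%), where chance gives about 1 in 20. In wild type these were Gad1 at 24 h replicate 1 (5.93), Sst (4.54) and Reln (4.86) at 24 h replicate 2, and the means of secretory granule genes (3.15), microglial markers (0.39) and p53 targets (2.66) at 48 h replicate 1, as well as the actin 3'/5' ratio of basal replicate 1 (2.23). In the knockout they were Gad2 at 48 h replicate 5 (1.71), Sst at 48 h replicate 1 (3.89), Tac1 (1.70) and secretory granule genes (2.19) at basal replicate 3, Reln (4.62) and joined GABAergic markers (1.95) at 24 h replicate 4, and GABA-A subunits at basal replicate 1 (1.51). Knockout 24 h replicate 1 stood apart in Nxph1 (0.19), ERK targets (2.37), XBP1-dependent genes (3.11) and ATF4 targets (2.28), and 24 h replicate 2 in progenitor genes (2.06) and p53 targets (3.24). The remaining cases were interneuron peptides at 48 h replicate 2 (3.09), pan-neuronal genes at 24 h replicate 5 (3.73) and oligodendrocyte markers at 24 h replicate 3 (0.86).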

How the results depend on the processing

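Chosen after the data were seen were the 48 h subsets, the term for 48 h replicates 3 to 5, the Gapdh covariate, the exclusion of X and Y genes and the linear scale. Outside the rule for named genes, values of single GABAergic genes were limited to response differences between genotypes only after a first run had shown more sign changes among them. Most results kept direction and call: of values for single genes 16590 did, 1571 lost the call, 12 gained one and 71 changed sign; of list values 2396 did, 240 lost the call (72 of them with an estimated correlation) and 26 changed sign. Of counts 235 stayed within 1.5 times and 88 did not, and of correlations 53 stayed and 3 moved. These totals include settings that could change little. With the lower floor all 710 gene values stayed, because on average only 0.0031% of tested genes lay at the floor. Leaving out 1 array gave 6853 of the unchanged gene values. Many named genes were picked for large changes past the threshold, so the totals give no rate for all genes. Counts of 48 h comparisons depended on which 48 h arrays were used and on the scaling, and genotype differences in response were few in every setting. The cause was not tested. Below, wild type stands before knockout, and comparisons are 24 h, 48 h and 48 h against 24 h.

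Values as deposited gave 275, 4379 and 4587 genes in wild type, 201, 3732 and 2008 in the knockout, 842, 877 and 882 between genotypes and 0 and 0 differences in response by limma. Joined GABAergic markers differed in response by 0.0199 and -0.058. List means were 0.0693 (wild type) and 0.13 (knockout) for lineage factors at 48 h and 0.0622 from 24 h in wild type, 0.0854, 0.17 and 0.20 for vascular markers at 48 h in wild type and knockout and from 24 h in wild type, 0.12 for p53 targets in the knockout and 0.22 from 24 h in wild type, 0.0881 for progenitor genes in the knockout and 0.22 for cell cycle genes from 24 h in wild type. Genes that changed sign were, in response difference, Calb1 (0.0327 and -0.0029), Calb2 at 24 h (0.011) and Cck at 48 h (-0.0023); at 48 h Phlda3 (0.0392), Sort1 (0.14) and Sox6 (0.0751) in wild type and Col1a2 (0.0114) and Gja1 (0.0156) in the knockout; from 24 h to 48 h in wild type Cdkn1a (0.0425), Col4a1 (0.0814), Mdm2 (0.0611), Rrm2 (0.10) and Sparc (0.0505); and Xbp1 at 24 h in the knockout (0.0357).

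With 48 h replicates 1 and 2 alone, 1023 and 136 genes passed in wild type, 1193 and 181 in the knockout, 911 between genotypes at 48 h and 1 in response difference; Calb2 (0.17), Nxph1 (0.0187) and Xbp1 from 24 h to 48 h in wild type (-0.0638) changed sign. With replicates 3 to 5 alone the counts were 1597 (wild type, 48 h against 24 h), 1178 (genotypes at 48 h) and 5 (response at 48 h), with joined GABAergic markers at -0.0355 and Tac1 at -0.0257. With a term for replicates 3 to 5 they were 1743 and 383 in wild type, 1211 and 157 in the knockout and 13 for the 24 h response, with Xbp1 at -0.0066 (knockout, 48 h) and -0.0046 (wild type, from 24 h). With the Gapdh covariate they were 1470 and 294, and 992 and 55.

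A threshold of 0.01 gave 545, 1686 and 409, then 364, 1263 and 182, between genotypes 1287, 1167 and 1137 and in response 2 and 1. At least 1.5-fold changes were 127, 428 and 96, then 96, 264 and 53, and 467, 433 and 485 between genotypes. Array weights gave 1677 in wild type (48 h against 24 h), 1584 and 1143 in the knockout (24 h, and 48 h against 24 h) and 22 and 33 in response, with Calb1 at 0.0164. The labels tie no dish to another by replicate number. Deviations from group means correlated with a median r of 0.0341 over 75 pairs of arrays of equal number in different groups and -0.0135 over pairs of unequal number. Of the former 23 exceeded 0.1, and 12 of 30 arrays correlated best with their own number, a hint from the data and not from the design. For response, the counts were 13 at 24 h with quantile normalization, 12 with 75th percentile scaling, 11 and 4 without trend, 11 with a replicate block, 4 and 3 with the stricter filter, 5 at 48 h without filter and 4 and 4 with the mean of probe sets.

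With quantile normalization Calb1 at 24 h was 0.0017 and Xbp1 at 48 h in the knockout -0.0118. Joined GABAergic markers at 48 h were -0.0111 with 75th percentile scaling, -0.0148 with the stricter filter, -0.0438 without filter and -0.0074 with the mean of probe sets. The response correlation was 0.454 and 0.675 without filter and 0.771 at 24 h with the stricter filter, where ATF4 targets differed by -0.0106 between basal genotypes. With the mean of probe sets the response differences were 0.18 for Abat at 48 h, 0.0733 and -0.11 for Calb1 and 0.32 for Slc32a1 at 48 h; Cyp51 (-0.0149) and Hyou1 (-0.0061) at 24 h in wild type, Syp from 24 h to 48 h (-0.14 and -0.10), Fn1 from 24 h to 48 h in the knockout (3.43e-04), Xbp1 at 48 h in the knockout (-0.0359) and from 24 h in wild type (-0.0195), and Ntrk2 at 24 h (0.0662) and Slc32a1 at 48 h (0.0347) between genotypes also changed sign.

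As each array was left out, response differences ranged from -0.10 to 0.0448 and -0.0126 to 0.11 for Calb1, -0.21 to 0.0159 and -0.17 to 0.0554 for Calb2, -0.0467 to 0.19 for Cck at 48 h, -0.0562 to 0.16 for Nxph1 at 24 h, -0.13 to 0.0158 for Slc32a1 at 48 h, -0.15 to 0.16 and -0.034 to 0.29 for Tac1 and -0.0323 to 0.0397 for joined GABAergic markers at 48 h; cell cycle genes in wild type from 24 h to 48 h ranged from -0.15 to 0.0085. Counts ranged from 561 (without knockout 24 h replicate 2) to 963 (without replicate 1) at 24 h in the knockout, from 594 (without wild-type 48 h replicate 3) to 1348 (without replicate 1) and from 348 (without knockout 48 h replicate 3) to 698 for 48 h against 24 h, and from 3 to 16 and 2 to 13 for response.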

Other observations

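The test on the linear scale was chosen only after the result was seen; the test of genes near Xbp1 was not.

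Among the named genes, the embryonic globins Hba-x, Hbb-y and Hbb-bh1, which form the tested erythroid list, fell from 24 h to 48 h of BDNF in the knockout (-1.68, -1.21 and -1.18) and in wild type (-0.89, -1.05 and -0.69). The retinoic acid binding protein gene Crabp2 fell under BDNF at 48 h in both genotypes (-1.17 and -0.81), with Crabp1 at -1.14 in wild type. The phagocyte gene Cd68 rose by 1.87 in wild type and 1.42 in the knockout at 48 h, while the microglial gene Tyrobp fell by 0.75 in wild type. The astrocyte gene Aldh1l1 rose between 24 h and 48 h by 1.01 and 0.96, and the apoptosis gene Bcl2l11 rose by 0.75 at 48 h in the knockout.

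A hypothesis was that BDNF adds less linear signal of GABAergic markers in the knockout, whose basal levels of several of them were lower. In units of the array median, 48 h of BDNF added 15.9 of Npy signal in wild type and 6.74 in the knockout, 25.1 and 8.88 of Sst and 13.9 and 7.92 of Calb1 (highest adjusted permutation p of the 3 = 0.00333 over 24 tests, n = 5). A lower basal level by itself lowers the signal added at a like fold change, and these 3 genes were picked with that level known. For these 3 the test decides nothing about the response to BDNF. Gad1 gained less in the knockout at 24 h (15.0 and 5.26) and 48 h (28.1 and 15.4, adjusted permutation p = 0.0179 and 0.0139). Gad2 did at 48 h only (1.98 and 1.16, adjusted permutation p = 0.0245). Their basal levels did not differ past the threshold, so that reason does not cover them. Slc32a1, Abat, Calb2, Cck, Tac1 and Nxph1 did not pass. No log2 response difference of Gad1 or Gad2 passed in limma, so the hypothesis stays open. Reln differed in the other direction, at -2.90 and 3.84 at 48 h (adjusted permutation p = 0.0202).

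A further hypothesis was that chromosome around Xbp1 from the strain of the targeted stem cells may contribute to the genotype differences. Up to 100 tested genes were taken on each side of Xbp1. This gave 124, because tested genes on the chromosome ran out on at least 1 side. Of these 124 genes, 19 (15.3%) differed in 1 direction at all 3 times. Among other genes 983 of 7306 did (13.5%, Fisher's exact test, two-sided p = 0.509). With so few genes this share cannot be told apart from that of the genome, so the hypothesis stays open.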
